A study of Homo sapiens with 6 samples.

How the data were processed

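The data are 6 RNA sequencing libraries of the ovarian cancer cell line Kuramochi, 3 transfected with a control siRNA and 3 with an siRNA against UCHL1. Cells were transfected with TransIT X2 and RNA was isolated with a miRNeasy kit, per the labels' protocols. The authors deposited raw counts of reads per Ensembl gene, 1 table per library, with no normalization. Reads were processed with Trimmomatic 0.33, TopHat2 2.0.0 and HTSeq 0.11.1 on GRCh38, per the submitters' processing notes. The annotation release, the strand setting of the counter and the read layout are not given in the sources used here, so overlapping and antisense genes cannot be told apart in the counts. Each table holds 58037 gene rows and 5 rows that name no gene. Of all counts in a table, alignments at more than 1 place made up 34.7% to 39.9%, reads in no gene 7.11% to 8.57% and ambiguous reads 1.66% to 1.88%, while the rows for low alignment quality and for unaligned reads were 0. These rows were left out of library sizes and tests. Since reads with several alignments are not in the gene counts, genes with near-identical copies or processed pseudogenes are undercounted and were treated as uncertain.

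Groups and replicate numbers came from the sample titles. Gene symbols came from a name table (56948 of the 58037 rows matched) and positions, transcript lengths, GC content and 3' UTRs from GENCODE release 29 on GRCh38, to which 57433 rows matched by identifier without its version and 53688 with it. Library depth was 8857280 to 11510521 counts in genes. With this depth and spread the median SE of a log2 fold change was 0.091, and the biological coefficient of variation was 4.68%. Replicates of a group differed by more than sampling noise in a chi-square test of their counts (chi-square per degree of freedom from 1.61 to 4.24), so each was counted as 1 sample.

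Genes were filtered with edgeR's filterByExpr and scaled by TMM, and the groups were compared with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3). P-values were adjusted by Benjamini-Hochberg over all 14166 genes tested, with a threshold of 0.05. Fold changes are siUCHL1 over siCTL, and the SE of a log2 fold change is its size divided by the square root of F. CPM (edgeR's cpm function) used the TMM-scaled library sizes of the tested genes. Before the data were examined, 38 gene lists were fixed, of which 36 had at least 5 members tested. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists tested, and again with an estimated correlation and with fry. Of the histone list, 2 members were not matched by name. For DESeq2, camera was run on that tool's gene statistics.

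The genes named were chosen by a rule also fixed before the data were examined: UCHL1, PSMA7 and APEH; the 12 largest rises and the 12 largest falls among called genes with a mean log2 CPM of at least 1, groups that do not overlap and a symbol that is not a clone or locus name; up to 4 members of each list with the smallest p; and the 5 genes with the smallest p outside the first sets. The clock genes in the closing section were chosen after the values of CIART and NR1D1 had been seen.

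The test was tried on simulated counts for the comparison of siUCHL1 with siCTL, drawn for the 14166 tested genes from the real means, library sizes and dispersions with 200 genes changed. It recovered 32% of 50 genes changed 1.2-fold, 82% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, with 10 calls among 13966 unchanged genes. DESeq2 1.42.0 recovered 30%, 72%, 76% and 98%. On simulated data camera called the 1 list that had been shifted and 0 others, the length and GC correction brought a planted trend with length from rho = 0.837 to 0.0487, and the 7-mer scan ranked a planted 7-mer 1. The counts for camera were drawn independently for each gene, so its 0 other calls do not show how it behaves where list members are correlated.

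The alternatives were RLE, upper-quartile and no normalization beyond library totals; no filter (at least 1 count) and a filter of at least 1 CPM in 3 libraries; DESeq2 and limma-voom; the replicate number as a block; each library left out in turn; an adjusted p under 0.01; a minimum fold of 1.2; and protein-coding genes only. A correction for transcript length and GC content was added after the data were seen. It removes from each library its spline trends (5 degrees of freedom each) against both, over the 14121 tested genes with a transcript. For the 7-mer scan, log2 fold change was regressed on the presence of each 7-mer in the 3' UTR, with 3' UTR length and GC as covariates, over 12098 genes with a 3' UTR of at least 50 bases, for 7-mers found in at least 50 genes (numpy 2.4.6, scipy 1.17.1). UCHL1 was left out of the scan. Protein levels, proteasome activity and reads were not analysed here.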

Results

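RNA was sequenced from Kuramochi, an established cell line of high-grade serous ovarian cancer, after transfection with a control small interfering RNA (siCTL, n = 3) or with an siRNA against UCHL1 (siUCHL1, n = 3). UCHL1 is a deubiquitinase, an enzyme that removes ubiquitin from other molecules, and the comparison asks which transcripts differ once it is silenced. Reads counted to genes came to 10348311, 11510521 and 10924119 in siCTL replicates 1, 2 and 3, and to 8857280, 11318967 and 10449330 in siUCHL1 replicates 1, 2 and 3. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Pearson's r of log2 counts scaled to library size (CPM) across genes lay between 0.9915 and 0.9946 for libraries of the same group and between 0.981 and 0.9831 for libraries of different groups. The first principal component held 60.9% of the variance and separated the groups. On the second, with 14.15%, siUCHL1 replicate 1 lay at -21.65, apart from siUCHL1 replicates 2 and 3 at 12.58 and 7.84.

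UCHL1 transcripts fell in every siUCHL1 library. The gene (ENSG00000154277.12) lies on the plus strand of chromosome 4, from 41256413 to 41268455 on GRCh38. Its level was 300.0 ± 3.36 CPM (SD, n = 3) in siCTL and 15.1 ± 1.84 CPM (SD, n = 3) in siUCHL1, a log2 fold change of -4.32 ± 0.07 (SE). The adjusted p from edgeR's quasi-likelihood test was 1.87e-20. Raw counts were 3098, 3494 and 3328 in the siCTL libraries and 138, 145 and 169 in the siUCHL1 libraries, so each library followed its label.

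PSMA7 and APEH, which the study is known to be concerned with, both fell. PSMA7 (ENSG00000101182.14, minus strand of chromosome 20, 62136735 to 62143440) encodes an alpha-ring subunit of the 20S proteasome core. Its level went from 303.3 ± 10.3 CPM (SD, n = 3) to 171.8 ± 7.55 CPM (SD, n = 3), a log2 fold change of -0.82 ± 0.05 (SE; edgeR adjusted p = 1.35e-10). APEH (ENSG00000164062.12, plus strand of chromosome 3, 49674002 to 49683963) encodes acylaminoacyl-peptide hydrolase, a cytosolic peptidase that acts on acetylated peptides. Its level went from 70.8 ± 2.99 CPM (SD, n = 3) to 26.3 ± 1.95 CPM (SD, n = 3), a log2 fold change of -1.43 ± 0.07 (SE; edgeR adjusted p = 1.08e-11). The 3' UTR of PSMA7 holds the 7-mer TCCATTT at 62136774 to 62136780, a sequence that also occurs in the coding part of the UCHL1 mRNA. It is a common sequence, held by the 3' UTRs of 2819 of 12098 genes searched.

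**Figure D1:**
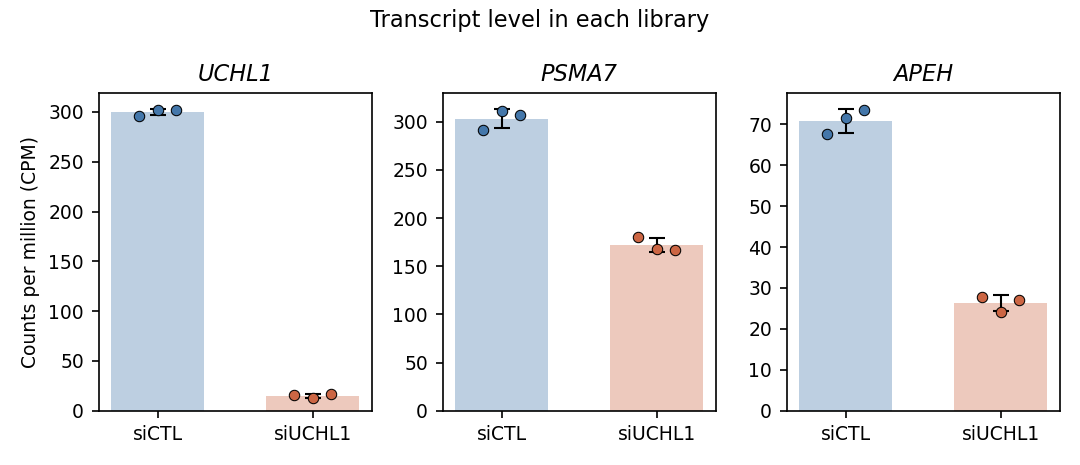
CPM (y axis, starting at 0) of UCHL1, PSMA7 and APEH in siCTL and siUCHL1. Points are the 3 libraries of each group, bars their mean and error bars the SD. The siUCHL1 libraries lie below all siCTL libraries for each gene, at a mean of 15.1 against 300.0 CPM for UCHL1, 171.8 against 303.3 for PSMA7 and 26.3 against 70.8 for APEH.

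Silencing was accompanied by changes in many genes, most of them small. Of 14166 genes tested, 6216 (43.9%) changed at an adjusted p under 0.05, 3214 higher and 3002 lower in siUCHL1. The balance turned with upper-quartile scaling (2781 higher, 3448 lower), with library totals (2834 and 3381) and with no filter (2935 and 3027). The median absolute log2 fold change of the changed genes was 0.384, and 4710 of them changed by less than 1.5-fold. At least 2-fold changes were found for 178 genes that rose and 160 that fell. In 7359 genes (51.95%) the CPM of the groups did not overlap, where chance gives 10% for 3 libraries against 3. Against a minimum fold of 1.2 the test called 2202 genes. Across genes the log2 fold change was correlated with GC content (Spearman's rho = -0.334) and little with transcript length (rho = 0.0132); genes are not independent replicates. When trends of each library against length and GC were removed, 6469 genes were called, of which 5042 were among the 6216.

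The largest rise among the genes named was that of IL6. IL6 and IL11, which encode secreted cytokines, rose by 2.64 ± 0.28 and 2.47 ± 0.27 (log2 ± SE) from 0.606 and 0.908 CPM. ATF3, a stress-induced transcription factor, rose by 2.58 ± 0.07 from 18.4 to 110.2 CPM, and KLF10, a zinc finger factor induced by TGF-beta, by 2.15 ± 0.06 from 36.9 to 163.9 CPM. The clock repressors CIART and NR1D1 rose by 2.39 ± 0.10 and 2.13 ± 0.11. PPP1R15A, which directs a phosphatase to eIF2-alpha, rose by 1.92 ± 0.10. The remaining genes of this set were the lipid receptor gene S1PR1 (2.57), GADD45B (2.43), the peptide hormone genes EDN1 (1.88) and ADM (1.84), and FOSB (1.80). Adjusted p over these 12 rises was at most 3.67e-07 in edgeR's test.

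The largest fall after UCHL1 itself was that of TBC1D5, a Rab GTPase-activating protein of the retromer pathway. It went from 97.9 ± 3.50 CPM (SD, n = 3) to 14 ± 1.08 CPM (SD, n = 3), a log2 fold change of -2.81 ± 0.08 (SE; edgeR adjusted p = 1.81e-16). A stretch of 15 bases in its transcripts is shared with the UCHL1 mRNA, and 218 other genes tested share at least 15 bases. BLMH, a cytosolic cysteine aminopeptidase, was next among the genes named, at -1.65 ± 0.09 (36.8 to 11.8 CPM). TMEM252 and PGM5, neighbours on chromosome 9, had log2 fold changes of -1.65 and -1.62 at means of at most 3.22 CPM. UBE2Q2, a ubiquitin-conjugating enzyme, fell by 1.54 ± 0.11, and PIR, an iron-binding nuclear protein, by 1.43 ± 0.10. SSPOP (-1.54), the adenylyl cyclase gene ADCY5 (-1.52), the Wnt-cleaving protease gene TRABD2B (-1.46), the sulfotransferase gene CHST1 (-1.46), the collagen receptor gene MRC2 (-1.45) and the sarcosine dehydrogenase gene SARDH (-1.43) completed the set. PGM5 and UBE2Q2 have near-identical copies and their values are uncertain. The 3' UTRs of BLMH, PGM5, UBE2Q2 and PIR also hold TCCATTT, as do 23.3% of genes outside PSMA7, APEH and the 12 largest falls. Of the 5 genes with the smallest p outside these sets, PLK2 (1.51), NUAK2 (1.495) and TXNIP (1.18) rose, and ANXA5 (-1.37) and NCS1 (-1.34) fell. ANXA5 holds 2 such sites and TXNIP 1.

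Genes of the 20S proteasome core other than PSMA7 tended to rise. Of 14 members 9 rose and 1, PSMA7, fell, and PSMA7 was the only member to fall with each of the scalings tried (TMM, RLE, upper quartile, library totals). PSMA3 rose by 0.34 ± 0.05 (log2 ± SE), PSMB7 by 0.31 ± 0.06 and PSMA5 by 0.28 ± 0.05. The list passed the camera test (median log2 fold change 0.179, adjusted p = 0.0394), but not with an estimated correlation (adjusted p = 0.521). Its adjusted p was 0.0941 without siCTL replicate 1, 0.0789 without siUCHL1 replicate 1, 0.191 with DESeq2 and 0.0843 after removal of length and GC trends. Among the 16 activators and assembly factors 7 rose and 1 fell, with the maturation factor POMP at 0.35 ± 0.06, PSMG2 at 0.42 ± 0.08 and PSME3 at 0.28 ± 0.05 (camera adjusted p = 0.0394; adjusted p = 0.281 with an estimated correlation). That call was lost without siCTL replicate 1 (0.0694), without siUCHL1 replicate 1 (0.0789) and with DESeq2 (0.0993). For the 19S regulator 7 of 19 rose and 1 fell, led by PSMD6 (0.50 ± 0.06) and PSMD8 (0.36 ± 0.06), and the list did not pass (adjusted p = 0.0969).

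**Figure D2:**
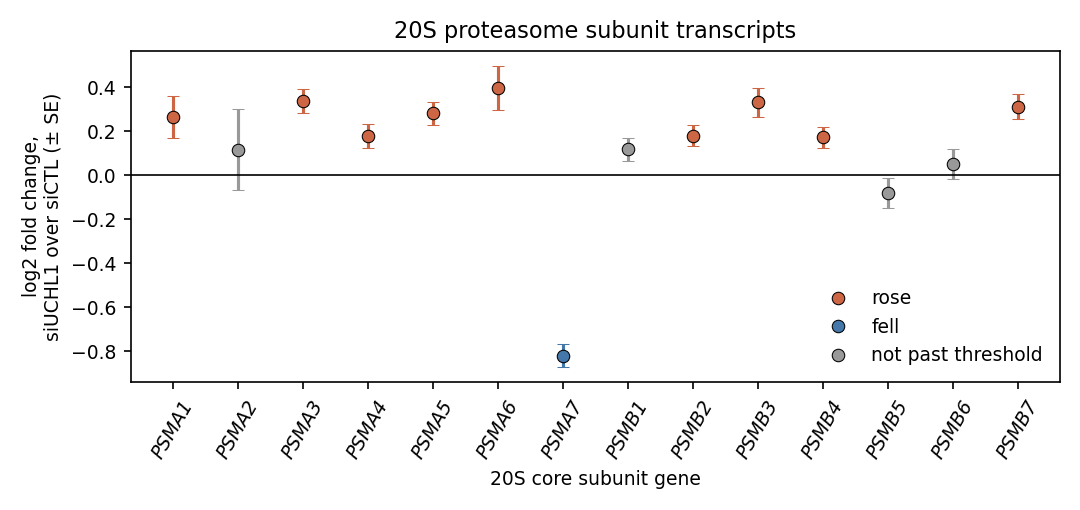
Log2 fold change of siUCHL1 over siCTL (y axis) for the 14 genes of the 20S core (x axis). Points are edgeR estimates from 3 libraries per group, bars the SE, and colours mark members that rose, fell or did not pass. PSMA7 lies at -0.82, while the 9 members that rose lie between 0.17 and 0.40.

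Other parts of the ubiquitin and peptide-handling machinery moved in both directions. Of 15 cytosolic peptidases tested 4 rose and 3 fell, and 1 rose and 3 fell with upper-quartile scaling and with library totals. APEH, BLMH and THOP1 (-0.48 ± 0.10) fell and LAP3 rose by 0.32 ± 0.06. The list did not pass (adjusted p = 0.809), with a median of 0.0295 and a mean of -0.183. Of 59 other deubiquitinases 19 rose and 10 fell (adjusted p = 0.162), with TNFAIP3, an inhibitor of NF-kappaB signalling, at 1.02, YOD1 at 0.59, USP15 at 0.59 and VCPIP1 at 0.56. Of 28 genes for ubiquitin and its activation 12 rose and 5 fell (adjusted p = 0.102). UBC rose by 0.60 and UBE2L6 by 0.44; UBC and RPS27A (0.32) have processed copies and are uncertain.

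Inflammatory, interferon-stimulated and immediate early genes rose together. Of 28 NF-kappaB and inflammatory genes 23 rose and 1 fell (median 0.659, camera adjusted p = 1.69e-08), including the chemokine gene CXCL8 (1.52), the apoptosis inhibitor BIRC3 (1.44), TNFAIP3 (1.02) and NFKBIA (0.82). Adjusted p was 0.16 with an estimated correlation. Of 39 interferon-stimulated genes 30 rose and 1 fell (median 0.417, adjusted p = 4.36e-09; adjusted p = 0.312 with an estimated correlation), among them IFIT2 (1.08), OAS1 (0.88), IFIT1 (0.80) and SAMD9 (0.76). Of 22 immediate early genes 18 rose and 2 fell (median 0.693, adjusted p = 4.88e-08; adjusted p = 0.16 with an estimated correlation). These included FOSB (1.80), FOSL1 (1.43), ZFP36 (1.22), which destabilises AU-rich mRNAs, and the phosphatase gene DUSP5 (1.11). YAP and TEAD targets also passed, with 9 of 19 risen and 2 fallen (median 0.188, adjusted p = 0.0275; adjusted p = 0.274 with an estimated correlation). ANKRD1 rose by 0.95, CCN1 by 0.93 and CCN2 by 0.69. Of 15 antigen presentation genes 6 rose and 5 fell (adjusted p = 0.516); TAP1 rose by 0.82 and B2M by 0.42, while HLA-B (0.39) and HLA-A (0.36) share reads with related genes and are uncertain.

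Stress-response lists were mixed. Of 36 ATF4 and integrated stress response genes 11 rose and 12 fell, with a median of -0.028 and a mean of 0.122 (adjusted p = 0.805), and 13 rose and 12 fell after removal of length and GC trends. ATF3 and PPP1R15A led the rises, with the amino acid transporter subunits SLC3A2 (0.775) and SLC7A5 (0.64). Of 37 endoplasmic reticulum chaperone and ERAD genes 5 rose and 16 fell (median -0.111, adjusted p = 0.0969). The protein disulfide isomerase genes PDIA4 and PDIA6 fell by 0.61 and 0.49, the sensor gene ATF6 fell by 0.49, and the co-chaperone gene DNAJB9 rose by 0.87. NRF2 and NRF1 targets passed, with 10 of 27 risen and 2 fallen (median 0.0928, adjusted p = 0.0394; adjusted p = 0.445 with an estimated correlation). HMOX1, which degrades haem, rose by 1.48, TXNRD1 by 0.69 and NQO1 by 0.54; FTH1 (0.45) has processed copies and is uncertain. The call was lost without siCTL replicate 1 (0.0526) and without siUCHL1 replicate 1 (0.0876). Of 24 cytosolic heat shock genes 6 rose and 4 fell (adjusted p = 0.459), with the small heat shock genes HSPB8 (1.57) and CRYAB (0.85) among the rises and FKBP4 (-0.555) among the falls. With upper-quartile scaling and with library totals 4 of the heat shock genes rose and 5 fell. Of 41 lysosome and autophagy genes 17 rose and 5 fell (adjusted p = 0.0969), the rises including the autophagy receptor gene SQSTM1 (0.58) and the proton pump genes ATP6V0D1 (0.60) and ATP6V1H (0.49). Of 32 mTOR pathway genes 7 rose and 10 fell (adjusted p = 0.911), with the Rag GTPase gene RRAGC at 0.57, LAMTOR3 at 0.48, the translation repressor EIF4EBP1 at -0.44 and AKT2 at -0.26. The mTOR list had a median of -0.0336 and a mean of 0.00339. After removal of length and GC trends 8 mTOR pathway genes rose and 2 fell (median 0.0313), and EIF4EBP1 and AKT2 were no longer called (adjusted p = 0.111 and 0.0623). Of 34 apoptosis regulators 13 rose and 5 fell (adjusted p = 0.129), with BIRC2 at 0.64 and MCL1 and BCL2L1 both at 0.42. Of 25 p53 targets 11 rose and 2 fell (adjusted p = 0.0511), with PPM1D at 1.14, GADD45A at 1.035 and BTG2 at 0.74.

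More S phase and mitosis genes fell than rose. Of 40 S phase and replication genes 17 fell and 5 rose (median -0.145, camera adjusted p = 0.00775; adjusted p = 0.221 with an estimated correlation). The nucleotide synthesis genes DHFR and TYMS fell by 0.82 and 0.54, LIG1 by 0.68 and POLE by 0.44. Of 38 mitosis genes 13 fell and 2 rose (median -0.11, adjusted p = 0.0275; adjusted p = 0.488 with an estimated correlation), with HMMR (-0.51), PLK1 (-0.38) and TOP2A (-0.31) lower and PTTG1 higher (0.36). Without siUCHL1 replicate 1 the mitosis list no longer passed (0.0876), while after removal of length and GC trends 26 of its genes fell and 2 rose. Of 33 homologous recombination genes 8 fell and 2 rose (adjusted p = 0.462), among them XRCC3 (-0.47), FANCC (-0.40) and RAD50 (-0.35). After removal of length and GC trends 15 of them fell and 1 rose. Of 15 replication-dependent histone genes 7 rose and 1 fell (median 0.251, adjusted p = 0.0394; adjusted p = 0.323 with an estimated correlation). H4C8 rose by 0.92, H2BC5 by 0.82 and H2AC6 by 0.69. Their near-identical copies make these values uncertain, and the list did not pass without siCTL replicate 1 (0.0526), without siUCHL1 replicate 1 (0.102) or with DESeq2 (0.0826).

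More genes of cholesterol and fatty acid synthesis fell than rose. Of 24 cholesterol synthesis genes 16 fell and 1 rose (median -0.24, camera adjusted p = 0.00119; adjusted p = 0.167 with an estimated correlation). LSS, which closes the sterol ring, fell by 0.76, the sterol sensor gene INSIG1 by 0.58, DHCR7 by 0.37 and DHCR24 by 0.29. Of 17 fatty acid synthesis genes 9 fell and 1 rose (median -0.216, adjusted p = 0.028; adjusted p = 0.274 with an estimated correlation), with the desaturase genes FADS2 (-0.77), FADS1 (-0.75) and SCD (-0.53) and the synthase gene FASN (-0.73) lower. The fatty acid list did not pass without siUCHL1 replicate 1 (0.068). Of 33 glycolysis and hypoxia genes 9 fell and 6 rose (adjusted p = 0.459), with CA12 (-0.74), PFKL (-0.59) and HK2 (-0.59) lower and ADM higher. Of these genes 10 fell and 11 rose after removal of length and GC trends.

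More genes for ribosomal proteins and for the nuclear part of respiration rose than fell. Of 75 cytosolic ribosomal protein genes 45 rose and 2 fell (median 0.165, camera adjusted p = 3.83e-05; adjusted p = 0.645 with an estimated correlation). RPL32 rose by 0.39, RPL39 by 0.36, RPL24 by 0.35 and RPS7 by 0.33; ribosomal protein genes have many processed pseudogenes and are uncertain. Of 46 nuclear genes for oxidative phosphorylation 20 rose and 3 fell (median 0.145, adjusted p = 0.0123; adjusted p = 0.531 with an estimated correlation), including COX6A1 (0.67), COX7B (0.41) and SDHB (0.29). Without siUCHL1 replicate 1 the adjusted p was 0.0625. Of the 13 genes encoded in mitochondria only MT-ND6, which lies on the opposite strand to most of the others, passed (-0.77; list adjusted p = 0.763). After removal of length and GC trends 7 of the 13 fell, among them MT-ND5 (-0.22). Of 32 MYC and ribosome biogenesis genes 5 rose and 8 fell (adjusted p = 0.763), with CAD (-0.48), MYBBP1A (-0.48) and TCOF1 (-0.44) lower and NOP58 (0.30) higher.

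**Figure D3:**
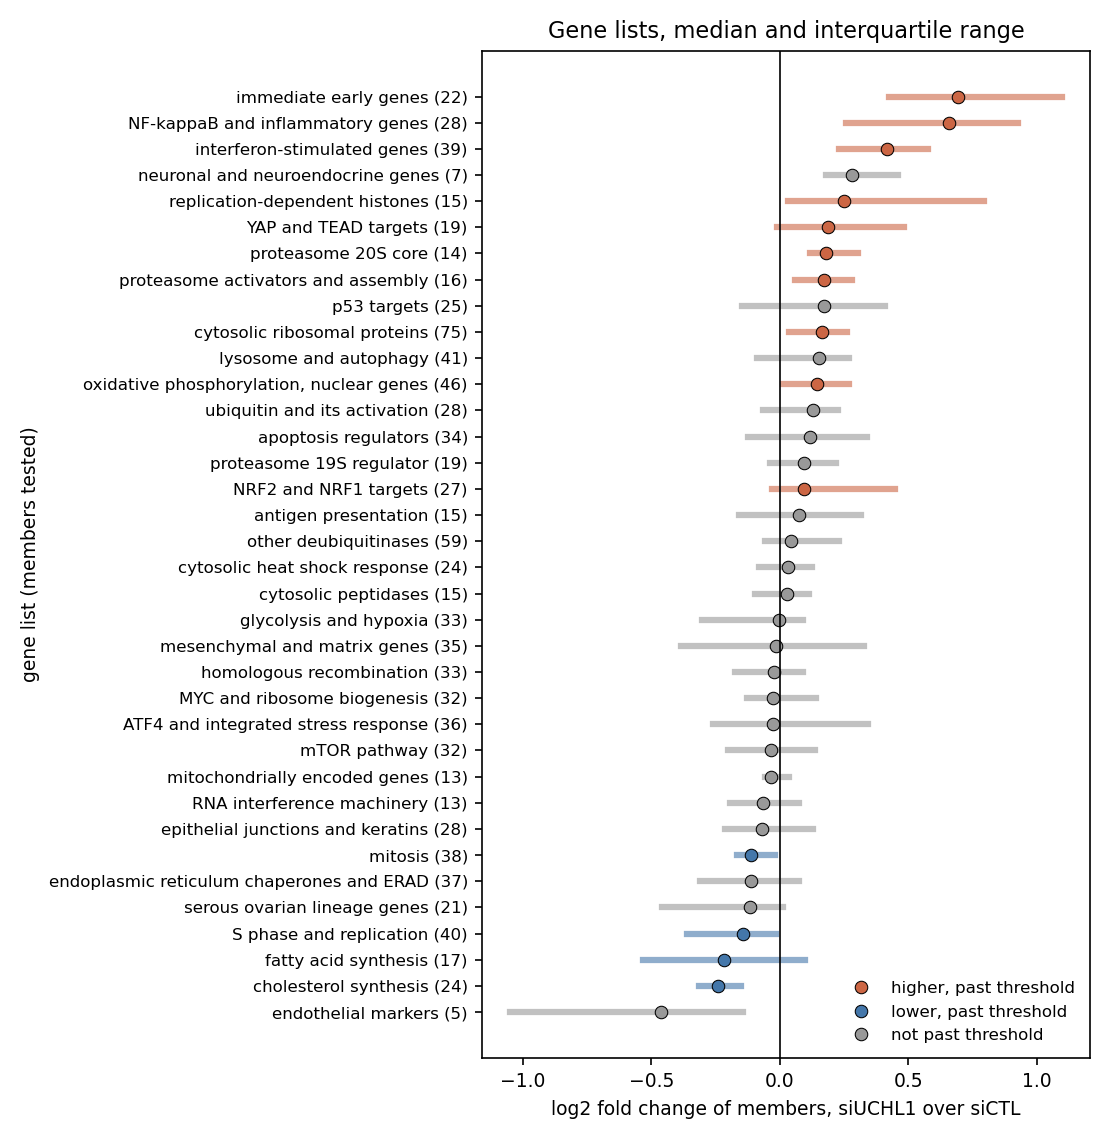
Median log2 fold change of siUCHL1 over siCTL (x axis) of the members of each of the 36 gene lists tested (y axis, members tested in brackets). Points are medians, bars span the interquartile range of members, and colours mark the 10 lists higher and 4 lower by camera with a preset correlation of 0.01. The immediate early (0.693), NF-kappaB (0.659) and interferon-stimulated (0.417) lists have the largest positive medians, and cholesterol synthesis (-0.24) and fatty acid synthesis (-0.216) the lowest among lists past the threshold.

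Lineage genes were mixed. Of 28 epithelial junction and keratin genes 6 rose and 5 fell (adjusted p = 0.809), with the transcription factor gene ELF3 at 1.06, PKP2 at 0.57, TJP1 at 0.32 and MUC1 at -0.46. After removal of length and GC trends MUC1 was at -0.01 (adjusted p = 0.903). Of 35 mesenchymal and matrix genes 10 rose and 11 fell (median -0.0133, mean 0.0502, adjusted p = 0.945), with SERPINE1 (1.29), THBS1 (0.73) and FN1 (0.61) higher and COL4A1 (-0.51) lower. Of 21 serous ovarian lineage genes 3 rose and 9 fell (adjusted p = 0.239); the 3 were OVGP1 (1.49), SPP1 (0.77) and CD24 (0.56), and LGR5 (-0.48) was among the falls. Of 13 RNA interference genes 4 fell and 0 rose (adjusted p = 0.33), namely AGO1 (-0.29), TNRC6A (-0.25), TNRC6B (-0.20) and XPO5 (-0.18). Of the 13 genes 3 rose and 6 fell after removal of length and GC trends. XPO5 was not called without siCTL replicate 3 (adjusted p = 0.0513). Markers of other cell types were few. No fibroblast or leukocyte marker had enough counts to be tested. Of 5 endothelial markers tested TIE1 (-1.05) and CDH5 (-1.17) fell, from 7.41 and 6.18 CPM (list adjusted p = 0.0859). Of 7 neuronal and neuroendocrine genes 4 rose (list adjusted p = 0.0616), INA (1.55), MAP2 (0.36), NCAM1 (0.23) and ENO2 (0.28). ENO2 was not called with DESeq2 (adjusted p = 0.0918), upper-quartile scaling (0.0637), library totals (0.0602) or no filter (0.0535), nor without siCTL replicate 1 (0.064), siCTL replicate 2 (0.117), siUCHL1 replicate 1 (0.0511) or siUCHL1 replicate 2 (0.151).

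In all, 14 of 36 lists passed camera with a preset correlation of 0.01, 10 higher and 4 lower. With an estimated correlation 0 passed, while 6 had an unadjusted p under 0.05. The estimate was above the preset 0.01 for ribosomal proteins (0.602), interferon-stimulated genes (0.249), the 20S core (0.225), oxidative phosphorylation (0.183) and mitosis (0.112). NRF2 and NRF1 targets (0.0831), histones (0.0569), immediate early genes (0.0403) and NF-kappaB genes (0.0389) also lay above it. Estimates were under 0.01 for proteasome activators (-0.0473), S phase (0.00422), YAP and TEAD targets (-0.0406), cholesterol synthesis (-0.00452) and fatty acid synthesis (-0.038). Fry, which tests whether members move on balance in a common direction, called 24. Without siUCHL1 replicate 1, 7 lists passed. Adjusted over the list alone, the members that rose and fell were 10 and 1 for the 20S core, 8 and 1 for the 19S regulator, 14 and 5 for ubiquitin and its activation, 5 and 17 for endoplasmic reticulum chaperones, 19 and 7 for lysosome and autophagy, and 11 and 3 for p53 targets. They were 5 and 19 for S phase, 1 and 17 for cholesterol synthesis, 3 and 10 for fatty acid synthesis, 22 and 4 for oxidative phosphorylation, 46 and 2 for ribosomal proteins, 3 and 8 for MYC and ribosome biogenesis, and 19 and 2 for immediate early genes. For the other lists tested, counts adjusted over the list alone equalled those over all genes tested.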

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

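The length and GC correction was chosen after seeing the data, and the other alternatives before. UCHL1 (log2 fold change from -4.40 to -4.21), PSMA7 (-0.86 to -0.78) and APEH (-1.47 to -1.28) stayed lower and past the threshold under all alternatives run. The count of changed genes lay between 4452 and 6821, except for 2202 with a minimum fold of 1.2, which by construction leaves out small changes. With DESeq2, 4968 genes were called, all of them among the 6216, and 550 had no adjusted p. With upper-quartile scaling 5783 of the 6216 remained called and 44.65% of calls were higher, against 51.7% with TMM; the median log2 fold change moved from -0.00868 to -0.0461. Genes changed at least 2-fold numbered 517 without a low-count filter, where more genes at low counts were tested. Of the other 162 named genes in 15 alternatives, 2404 of 2430 values kept their direction and side of the threshold, 13 lost and 13 gained a call, and 0 changed direction. The gains were those of MT-ND5 in 6 alternatives, MT-ND3 and MT-ATP8 in 3 each and KDR in 1. The lowest r within a group was 0.9928 with a prior count of 5.

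Gene lists depended more on the setting. With an estimated correlation 0 lists passed: adjusted p was 0.521 for the 20S core, 0.281 for proteasome activators, 0.445 for NRF2 and NRF1 targets, 0.221 for S phase, 0.488 for mitosis, 0.312 for interferon-stimulated genes, 0.16 for NF-kappaB genes and for immediate early genes, 0.274 for YAP and TEAD targets and for fatty acid synthesis, 0.167 for cholesterol synthesis, 0.531 for oxidative phosphorylation, 0.645 for ribosomal proteins and 0.323 for histones. The estimated correlation was under the preset 0.01 for proteasome activators, S phase, YAP and TEAD targets, cholesterol synthesis and fatty acid synthesis. There the lost call does not reflect a higher correlation. For all other called lists the estimate was above 0.01, up to 0.602, so their preset p may be too small. The estimated form takes its degrees of freedom from the 6 libraries, so a lost call does not show that a list did not move. Fry called 24 lists, but not the 20S core (0.0526) or ribosomal proteins (0.0665). DESeq2 did not call the 20S core (0.191), proteasome activators (0.0993) or histones (0.0826), and the length and GC correction did not call the 20S core (0.0843). With 1 library left out, 7 to 16 lists passed. Adjusted p then ranged from 0.0304 to 0.0941 for the 20S core, 0.0183 to 0.0789 for proteasome activators, 0.0183 to 0.0876 for NRF2 and NRF1 targets, 0.0123 to 0.0876 for mitosis, 0.0183 to 0.068 for fatty acid synthesis, 0.00377 to 0.0625 for oxidative phosphorylation and 0.0183 to 0.102 for histones. The lowest count, 7, came without siUCHL1 replicate 1, where 6821 genes were called, and the cause was not tested.

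Whether the replicate numbers pair the samples is not given in the labels and was not settled here. Deviations of libraries with the same number from their group means correlated at -0.0982, -0.111 and -0.00364. For different numbers the correlations ran from -0.00416 to 0.107, so a shared number went with no shared deviation. With the replicate block 5713 genes were called, 5680 of them among the 6216, and 9 lists passed. The 20S core (0.0546), proteasome activators (0.0546), NRF2 and NRF1 targets (0.052), mitosis (0.0525) and fatty acid synthesis (0.0546) were not called with the block. The block leaves fewer degrees of freedom, and whether that ended these calls was not tested. At this depth a 1.2-fold change was recovered in 32% of simulated genes, so a gene not called is not shown to be unchanged. The simulation changed only 200 of 14166 genes, which makes the adjusted threshold stricter than in the data, where 6216 were called. The share recovered in the data may therefore be higher than 32%.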

Other observations

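The seed tests of PSMA7 and APEH alone were chosen after the 7-mer scan had been seen, and the length and GC correction and the clock genes after the data had been seen. The 10 ways to divide the 6 libraries into 3 and 3 are too few for a share under 0.05. The real division gave 6216 changed genes and 338 changed at least 2-fold, and the highest of the 9 others gave 0 of each by edgeR, with at most 604 genes at an unadjusted p under 0.05. Only 1 of the 10, the real one, gave as many. Each of the 9 others holds libraries of both groups on each side, so the group difference widens the spread within its sides. Its 0 calls could thus be foreseen and are not a chance level. For gene lists the real division gave 14 past the threshold and the highest other 12, again with 1 of 10 reaching the real count. Camera with a preset correlation thus also called lists in divisions that called no gene. The 9 others mix the groups in the same proportion, yet called from 1 to 12 lists, so these counts also depended on which libraries shared a side. These divisions keep part of the group difference, so how many of their list calls are false cannot be told.

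Some circadian genes rose besides CIART and NR1D1. Of 11 other clock repressors and E-box targets, genes that the CLOCK and BMAL1 factors drive, 7 rose and 0 fell, with a median log2 fold change of 0.398 (interquartile range 0.344). CRY2 rose by 0.93 ± 0.08 (log2 ± SE), CRY1 by 0.71 ± 0.09, PER1 by 0.57 ± 0.07 and TEF by 0.49 ± 0.12, while PER2 (0.01 ± 0.07) and PER3 (-0.08 ± 0.06) did not pass. The activators CLOCK (0.08), BMAL1 (0.22) and NPAS2 (0.19) did not pass either. A candidate explanation is a coordinated rise of clock output, for which a median of at least 0.3 was set beforehand. The libraries carry no time of harvest, so a difference in clock phase between dishes remains open.

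To weigh seed pairing of the siRNA with other mRNAs against the falls of PSMA7, APEH and the 12 largest falls, 16208 7-mers were scanned, 1390 of them in the UCHL1 mRNA, and the 1 whose presence in 3' UTRs went most with a fall was TCCATTT (t = -10.47, over 2819 genes), which lies in the UCHL1 coding sequence in exon 7 of 9 (chromosome 4, 41263244 to 41263250, GRCh38); the strongest rise had t = 4.71. Genes with the 7-mer followed by A, the form an 8-base seed site takes, had a median log2 fold change of -0.03, those with the 7-mer alone 0.00458 and those with no site 0.01. As the 7-mer was picked for its fall, only carriers were compared, with 3' UTR length and GC as covariates. Those followed by A lay at -0.0971 ± 0.0162 (log2 ± SE, 750 genes) against 2068 genes with the 7-mer alone. Of 1295 other UCHL1 7-mers, 0% had a t as low. This comparison is not free of the scan, where CCATTTA, the same site shifted onto its A, had ranked 2 (t = -8.67). The other UCHL1 7-mers were not picked for a fall, so the 0% is not an independent chance level. Off-target pairing of the UCHL1 siRNA would give such values, but they do not test it apart from the scan. PSMA7, left out of this comparison, carries the longer form and is the only 20S core gene that does. The core gene PSMA5 carries the 7-mer not followed by A and rose by 0.28 ± 0.05 (log2 ± SE). Only 3.47% of genes with the 7-mer followed by A lay below PSMA7, against 1.499% with the 7-mer alone and 1.99% with no site. Of the 14 genes 5 carry TCCATTT against 23.3% of other genes (one-sided Fisher's exact p = 0.21). This does not decide the matter for the set. APEH holds 1 UCHL1 7-mer past the Bonferroni threshold for a fall, and 22.8% hold as many or more among 1318 genes with a similar 3' UTR length. That 7-mer is TTCCATT, which is TCCATTT shifted by 1 base, so APEH holds only part of the same site. Of the 4 passing UCHL1 7-mers, only AAGAAGT (t = -5.99) does not overlap TCCATTT. Length and GC do not account for the median fall of the 14 genes, which kept 87.7% after the correction (-1.31 against -1.49). All 14 stayed past the threshold, with PSMA7 at -0.78 and APEH at -1.28. The interquartile range of the 14 widened from 0.165 to 0.433, so the correction changed members unequally. Their median GC was 54.1% against 48% for all genes. Whether PSMA7 and APEH fell through loss of UCHL1 or through the siRNA itself stays open. The siRNA sequence is not among the labels and a rescue was not analysed here.

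TBC1D5, the largest fall of the set, holds 0 sites of TCCATTT and 0 of the other passing UCHL1 7-mers in its 3' UTR of 3801 bases, which counts against seed pairing there. It shares 15 bases with the UCHL1 mRNA, and 2.54% of 1612 genes of similar transcript length share as many or more. This met the bound set beforehand for a candidate explanation, cleavage by an siRNA that covers this stretch. TBC1D5 had been picked for its fall. The place of the stretch in the UCHL1 mRNA was not compared with that of TCCATTT, so whether a single siRNA could cover both is not known. Among 218 other genes that share at least 15 bases 27.5% fell, against 21.1% of the remaining genes, and 2 fell at least 2-fold, so a shared stretch alone did not go with a large fall. This stays a hypothesis.

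The rise of interferon-stimulated, NF-kappaB and immediate early genes was seen in each siUCHL1 library. Over all 88 members the median log2 difference from siCTL was 0.492, 0.497 and 0.486 in siUCHL1 replicates 1, 2 and 3, so the lowest reached 95.7% of the overall median, against a single library as its source. After removal of length and GC trends the members kept 101% of their median (0.515 against 0.512), against such a trend. Sensing of the UCHL1 siRNA as foreign RNA may differ from that of the control siRNA, and this could not be separated from a response to UCHL1 loss, since siRNA and group coincide.

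The small rises of ribosomal protein, oxidative phosphorylation, proteasome and histone genes were weighed against a length or GC trend, since their transcripts are short (median 1270 against 3285 bases for all genes tested). With trends fitted on genes outside the lists, the 166 members kept 96.5% of their median (0.166 against 0.172), which argues against a length or GC trend as the source. For the 20S core the median went from 0.179 (interquartile range 0.188) to 0.144 (0.122). Its camera adjusted p went from 0.0394 to 0.073, so it was no longer called. Of its members 9 rose after the correction, and why the call was lost was not tested. Reads shared with pseudogenes stay open and were not tested.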
